A study of Blumeria hordei and Puccinia triticina with 18 samples.

How the data were processed

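Total RNA was extracted from infected leaves with a miRNeasy kit and sequenced as single 125 bp reads on a HiSeq 2000, per the labels' protocols. The series holds 18 libraries: 6 of leaf rust and 12 of powdery mildew. Rust libraries came from 2 groups and mildew libraries from 4 groups, with 3 libraries in each, taken from the sample titles. The labels call the 3 libraries of a group biological replicates. Barley plants were 3 weeks old when inoculated.

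The deposited files hold raw counts of reads per gene, which the authors made with featureCounts 1.4.6, per the file headers. The headers show no option for strand, for reads that map to several places or for reads that overlap several genes. With that tool's defaults, reads on either strand count, and reads that map to several places or hit several genes are left out, so genes with a near-identical copy may be undercounted. None of the named genes overlaps another gene model in the annotation. The gene models are those of assembly ASM15152v1 for rust and EF1 for mildew, per the file headers, and coordinates are given on these. STAR and edgeR are named in the submitters' processing notes without versions. Whether reads were first matched to the host genome is not given in the sources used here. In each file 1 row had no gene ID. It held 0.00105% to 0.00581% of a library's counts and was left out of library sizes and tests.

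Among the rust models, 95.9% of those with a PTTG_ identifier have a length that is a multiple of 3, so their length is a coding length. Among the mildew models this share is 65.3% for bgh identifiers, 74.6% for bghG and 27.4% for EFBGRG. All 328 EFBGRG models have 1 exon, with a median length of 73 bp, so theirs is not taken as a coding length. The files do not pair gene IDs with names or products, and no other annotation was used here. For that reason the 30 gene lists fixed beforehand, pathways and host markers among them, could not be tested. In place of pathways, 14 classes of gene models were tested in each comparison: 1 exon, 5 or more exons, a summed exon length under 600 bp, one of 3000 bp or more, and the 10 scaffolds with the most tested genes.

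Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, robust, TMM factors) in R 4.3.3, after filterByExpr with a minimum count of 10. This kept 7389 rust genes and 5972 mildew genes. The 6 rust libraries were fitted alone, and the 12 mildew libraries in one model of 4 groups, from which the host comparison at each stage, the stage comparison on each host and the interaction were taken. P-values were adjusted by Benjamini-Hochberg, and an adjusted p below 0.05 was a call. Fold changes are Lr34 over susceptible, or 5 dpi over 48 hpi. An interaction is the host log2 fold change at 5 dpi minus that at 48 hpi. CPM values use TMM-scaled library sizes. Classes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with the correlation estimated from the data. The planned fry test, which tests a class by itself and not against the other genes, was run beside it. Totals were compared by exact two-sided permutation, which cannot go below p = 0.1 with 3 against 3 libraries. Counting intervals are exact 95% intervals and cover counting error only, as does the limit of 3 counts set for a count of 0.

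Named genes followed a rule set before the data were examined: called genes whose libraries do not overlap between the groups, with a mean log2 CPM of 2 or more, the 12 highest and the 12 lowest fold changes. For the interaction, which does not compare 2 groups, the condition on overlap was not applied. Up to 4 members of each tested list were to be added. Where no gene passed, the 3 with the smallest p of each sign were to be named and said to have missed the threshold. Where IDs have no names, the rule allows at most 2 in each direction, which applied here.

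Replicate libraries were compared by a chi-square test of their counts. All pairs differed by more than sampling noise, with chi-square per degree of freedom from 2.15 to 107, so each library counts once. The alignment that was counted carries a second mapping tag in 2 libraries, the first Lr34 rust library and the second susceptible mildew library at 48 hpi, and a first tag in the other 16, per the file headers. What the tags mean is not given in the sources used here, so the mapping may have differed for these 2 libraries. For the second susceptible mildew library at 48 hpi the alignment name otherwise equals that of the first. Over 1442 genes with 10 to 40 counts in both together, the chi-square per gene of this pair was 2.89 (95% bootstrap interval 2.70 to 3.09). The same reads aligned again would give a value near 0, so they were kept as 2 libraries; this check was added after the data were examined. The labels give no sequencing batch or date.

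The test was tried on simulated counts with the real library sizes, a single mean per gene and 200 changed genes. Of genes changed 2-fold it recovered 57% for rust, 42% for the 48 hpi host comparison, 90% for the 5 dpi host comparison, and 61% and 64% for the stage comparisons on susceptible and Lr34 barley. Of genes changed 4-fold it recovered 92%, 90%, 99%, 96% and 95% in the same order. False calls were 7 of 162 called genes for rust, 1 of 142 and 18 of 226 for the host comparisons at 48 hpi and 5 dpi, and 6 of 167 and 7 of 178 for the stage comparisons. The class test found the planted class and called 0 of 20 unchanged classes in each comparison. The planted class was shifted by less than 2-fold, and its genes count among the called ones but not as false calls. Simulated means were taken over all libraries of a fungus. Simulated noise was independent between genes, so deviations linked to gene length were not part of it. Each gene also had the same simulated spread in all groups of a fungus. The real mildew groups differed, with coefficients of variation of 0.202 and 0.276 at 48 hpi and 0.145 and 0.153 at 5 dpi (Lr34, susceptible). Recovery may therefore be overstated for the 48 hpi host comparison and understated for the 5 dpi one.

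The alternatives were RLE size factors, no filter on low counts, a minimum count of 50, DESeq2 1.42.0, limma-voom, a fold change of at least 2, an adjusted p below 0.01, the replicate number as a block, a fit of the compared groups alone, total counts without the 10 most abundant genes, and leaving out each library in turn. Thinning of all libraries of a fit to the shallowest total (median of 5 draws), and the alternatives for the classes, were added after the data were examined. Splits of the libraries were refitted, all 10 for each 3 against 3 comparison and 100 drawn for the interaction. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.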

Results

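Transcripts of 2 biotrophic fungi were counted in infected cereal leaves with and without Lr34, a wheat ABC transporter gene that gives partial and durable resistance to several rusts and to powdery mildew. The leaf rust fungus Puccinia triticina was sampled in the field at a late sporulating stage from susceptible wheat and from Lr34 wheat, with 3 libraries on each host. These infections carried a mixture of 16 isolates. The barley powdery mildew fungus (Blumeria graminis in the labels, isolate K1) was sampled in the greenhouse on susceptible barley and on Lr34 barley, at 48 hours post inoculation (hpi) and at 5 days post inoculation (dpi), with 3 libraries in each of the 4 groups. The series asks whether the fungal transcriptome responds to Lr34 in the host, and the mildew layout adds the change between the stages.

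Rust libraries held 9.11 to 15.0 M counts (M, mega) assigned to the 13082 rust gene models. Mildew libraries at 48 hpi were much shallower, with 0.310 to 1.27 M counts over 7375 gene models. At 5 dpi they held 7.47 to 9.80 M counts on susceptible barley and 2.11 to 5.00 M on Lr34 barley. The gene with the most counts took at most 1.3% of any library. A gene with 0 counts could still lie at up to 0.329 counts per M (CPM) in the shallowest rust library and at up to 9.69 CPM in the shallowest mildew library, counting error only.

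**Figure D1:**
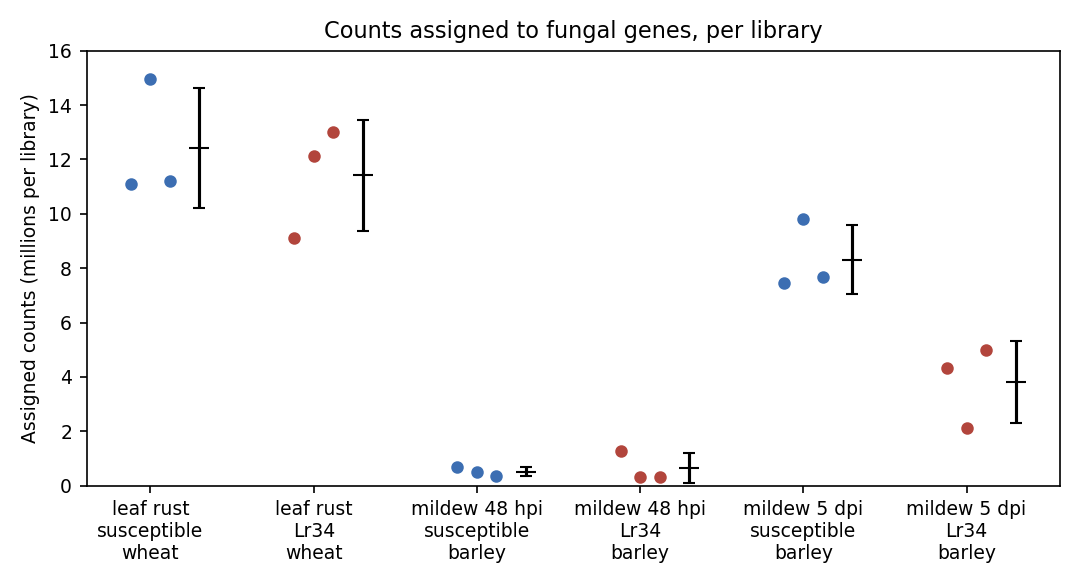
Counts assigned to fungal genes (y axis, M per library) in the 6 groups (x axis); each point is 1 library, blue for susceptible hosts and red for Lr34 hosts, and the bar beside it is the mean ± SD (n = 3). Mildew libraries at 48 hpi hold 0.310 to 1.27 M counts, and at 5 dpi each Lr34 library lies below each susceptible one.

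In leaf rust, the comparison of Lr34 wheat with susceptible wheat asked whether sporulating rust expresses other genes on the resistant host. None of 7389 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and the smallest adjusted p was 0.984. At an unadjusted p under 0.05 there were 230 genes, 3.11% of those tested. DESeq2 called 3 genes and limma-voom 0. Among the 3 were PTTG_07625 and PTTG_03794 (DESeq2 adjusted p = 0.00405 each). The genes named here missed the threshold in edgeR and were chosen by their p-value. PTTG_06615 (scaffold GG705501, 284501 to 285156, minus strand, 2 exons, assembly ASM15152v1) was at 332 ± 315 CPM (SD, n = 3) on Lr34 wheat and 30.8 ± 7.66 CPM on susceptible wheat. Its log2 fold change was 3.42, and 2.41 without Lr34 library 3. PTTG_07625 (scaffold GG705537, 12584 to 13000, minus strand, 3 exons) was at 254 ± 109 CPM on Lr34 wheat and 76.3 ± 36.6 CPM on susceptible wheat. In the other direction, PTTG_03794 (scaffold GG705431, 645948 to 648663, plus strand, 10 exons) was at 617 ± 93.0 CPM against 1260 ± 248 CPM. PTTG_06535 (scaffold GG705507, 7555 to 11223, minus strand, 9 exons) was at 60.4 ± 5.99 CPM against 101 ± 4.96 CPM. Total rust counts were 11.4 ± 2.05 M on Lr34 wheat and 12.4 ± 2.20 M on susceptible wheat (exact two-sided permutation test, p = 0.6, where 3 against 3 libraries allow no p below 0.1).

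The precision of the rust comparison bounds most genes. For 74.2% of tested genes the 95% confidence interval of the fold change lay within 2-fold in either direction, and for 97.8% within 4-fold. Short gene models, with a summed exon length under 600 bp, had a median log2 fold change of 0.10 against -0.03 for the other genes (camera, adjusted p = 1.2e-07, 1370 genes). With an estimated correlation between genes the adjusted p was 0.517, and without the first susceptible library it was 0.443 with a median of 0.04. That library was relatively low for short models, with a median log2 deviation of -0.25 from the other susceptible libraries. Models of 3000 bp or more had a median of -0.15 (adjusted p = 3.18e-06, 601 genes), with an adjusted p of 0.664 under an estimated correlation and 0.939 without the same library. Models with 1 exon had a median of 0.07 (adjusted p = 0.00957, and 0.517 with an estimated correlation), and those with 5 or more exons a median of -0.06 (adjusted p = 0.000153, and 0.307 with an estimated correlation). Without the first susceptible library 0 of these 4 classes were called, and without the second Lr34 library 2. Leaving out the second Lr34 library also raised the number of called genes from 0 to 5, PTTG_06615 among them (adjusted p = 0.000324).

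At 48 hpi, when the mildew fungus has formed its first feeding structures, 2 of 5972 tested genes differed between Lr34 and susceptible barley. BGHDH14_bghG006495000001001 (scaffold HF943487, 392455 to 393656, plus strand, 3 exons, annotation EF1) was higher on Lr34 barley, at 76.1 ± 35.1 CPM against 12 ± 0.941 CPM (n = 3 each). Its log2 fold change was 2.75 (SE 0.44, adjusted p = 0.0238, edgeR quasi-likelihood test). BGHDH14_bgh05058 (scaffold HF943495, 46934 to 48224, minus strand, 3 exons) was lower on Lr34 barley, at 145 ± 24.8 CPM against 337 ± 80.2 CPM, with a log2 fold change of -1.25 (SE 0.22, adjusted p = 0.0430). Both values rest on shallow libraries: the first gene had 178 counts on Lr34 barley and 16 on susceptible barley over all 3 libraries of a group.

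Short gene models at 48 hpi had a median log2 fold change of -0.39 on Lr34 barley against 0.03 for the rest (adjusted p = 1.46e-08, 485 genes). Models of 3000 bp or more had a median of 0.32 (adjusted p = 2.76e-17, 572 genes). For both classes the adjusted p was 0.460 with an estimated correlation. The second susceptible library stood apart from its group in these classes, with a median log2 deviation of 0.80 in short models and -0.59 in long ones. Without it the short models had a median of -0.08 (adjusted p = 0.212) and the long models a median of 0.20 (adjusted p = 5.02e-06). Total fungal counts were 0.635 ± 0.550 M on Lr34 barley and 0.508 ± 0.165 M on susceptible barley (exact two-sided permutation test, p = 1). Lr34 library 1 held 1.27 M, while Lr34 libraries 2 and 3 held 0.324 and 0.310 M, less than each susceptible library.

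The count of 2 genes at 48 hpi depended on the tool and on the libraries fitted. A fit of the 48 hpi groups alone called 0 genes, with adjusted p = 0.0671 for BGHDH14_bghG006495000001001 and 0.146 for BGHDH14_bgh05058. DESeq2 called 158 genes and limma-voom 0, and 1093 genes had an unadjusted p under 0.05. Leaving out Lr34 library 1, 2 or 3 gave 0, 1 and 0 genes, and leaving out susceptible library 1, 2 or 3 gave 4, 0 and 122. BGHDH14_bghG006495000001001 lost its call without Lr34 library 1 (adjusted p = 0.235) or 3 (0.0562) or susceptible library 1 (0.0506) or 2 (0.0931). BGHDH14_bgh05058 lost it without Lr34 library 1 (0.235), 2 (0.0839) or 3 (0.0910) or susceptible library 2 (0.0931). The 95% confidence interval lay within 2-fold for 52.7% of genes, so a change of that size was not bounded for the rest. Of genes changed 2-fold in simulated counts, 42% were recovered in this comparison. Fit and simulation shared 1 spread per gene over all mildew groups, with a common coefficient of variation of 0.180. The 48 hpi groups had 0.202 on Lr34 and 0.276 on susceptible barley, so the 42% may be too high and the intervals too narrow.

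At 5 dpi, 27 mildew genes differed between the hosts, 10 of them higher and 17 lower on Lr34 barley. The sizes were moderate, with a median absolute log2 fold change of 1.05, and 19 of the 27 changed at least 2-fold. Of the 27, 22 were also called between the stages on susceptible barley and 18 on Lr34 barley, where 36.1% and 21.9% of all tested genes were called. The stage comparisons share 5 dpi libraries with the host comparison, which favours such overlap. EFBGRG00000000232 (scaffold HF943267, 68 to 1866, plus strand, 1 exon) was higher on Lr34 barley, at 23.8 ± 19.9 CPM against 2.53 ± 1.03 CPM, a log2 fold change of 3.08 (SE 0.57, adjusted p = 0.0157). Its own length of 1799 bp is not a multiple of 3, and in its identifier series 27.4% of lengths are, so it may not be a coding gene. Host reads counted in it were not excluded. BGHDH14_bgh01363 (scaffold HF943522, 487892 to 488521, minus strand, 2 exons) was also higher, at 50.7 ± 17.9 CPM against 14.6 ± 3.97 CPM, a log2 fold change of 1.82 (SE 0.36, adjusted p = 0.0191). BGHDH14_bgh05191 (scaffold HF943528, 321480 to 322892, minus strand, 3 exons) was lower, at 6.65 ± 1.10 CPM against 23.1 ± 6.58 CPM, a log2 fold change of -1.79 (SE 0.32, adjusted p = 0.0118). BGHDH14_bgh03262 (scaffold HF943516, 397760 to 398679, plus strand, 3 exons) was lower too, at 22.1 ± 8.01 CPM against 67.0 ± 27.4 CPM, a log2 fold change of -1.59 (SE 0.32, adjusted p = 0.0206).

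For most mildew genes at 5 dpi the host difference was bounded closely, since 87.0% of the 95% confidence intervals lay within 2-fold and 99.5% within 4-fold. Short gene models did not differ from the rest, with a median log2 fold change of -0.01 (adjusted p = 0.966). Models of 3000 bp or more had a median of 0.10 (adjusted p = 0.00245, and 0.976 with an estimated correlation), and 0 classes were called without Lr34 library 2 or without susceptible library 3. DESeq2 called 134 genes, 82 higher and 52 lower, limma-voom 141, and a fit of the 5 dpi groups alone 117, which held 21, 26 and all of the 27. DESeq2 gave no adjusted p for BGHDH14_bgh05191 and BGHDH14_bgh03262. Leaving out Lr34 library 1 or 3 gave 14 and 2 genes, and leaving out susceptible library 1, 2 or 3 gave 17, 5 and 17. The call of EFBGRG00000000232 ended without Lr34 library 2 (log2 fold change 2.25, adjusted p = 0.0774) and without susceptible library 1 (0.0511) or 3 (0.0703), and also under limma-voom (0.101) and with no filter on low counts (0.0569). The call of BGHDH14_bgh01363 ended without Lr34 library 1 (0.0610) or 3 (0.313) and without susceptible library 1 (0.0749) or 2 (0.165). That of BGHDH14_bgh05191 ended without Lr34 library 3 (0.178) or susceptible library 1 (0.0694), and that of BGHDH14_bgh03262 without Lr34 library 2 (0.0850) or 3 (0.365) or susceptible library 1 (0.144).

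Fewer fungal counts were recovered from Lr34 barley at 5 dpi. The totals were 3.81 ± 1.51 M on Lr34 barley and 8.32 ± 1.3 M on susceptible barley, a 2.31-fold difference between geometric means. Each Lr34 library lay below each susceptible library, which gives p = 0.1 in an exact two-sided permutation test, the smallest p that 3 against 3 libraries allow. The files hold counts for fungal genes only, so these totals also depend on how deeply each library was sequenced.

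**Figure D2:**
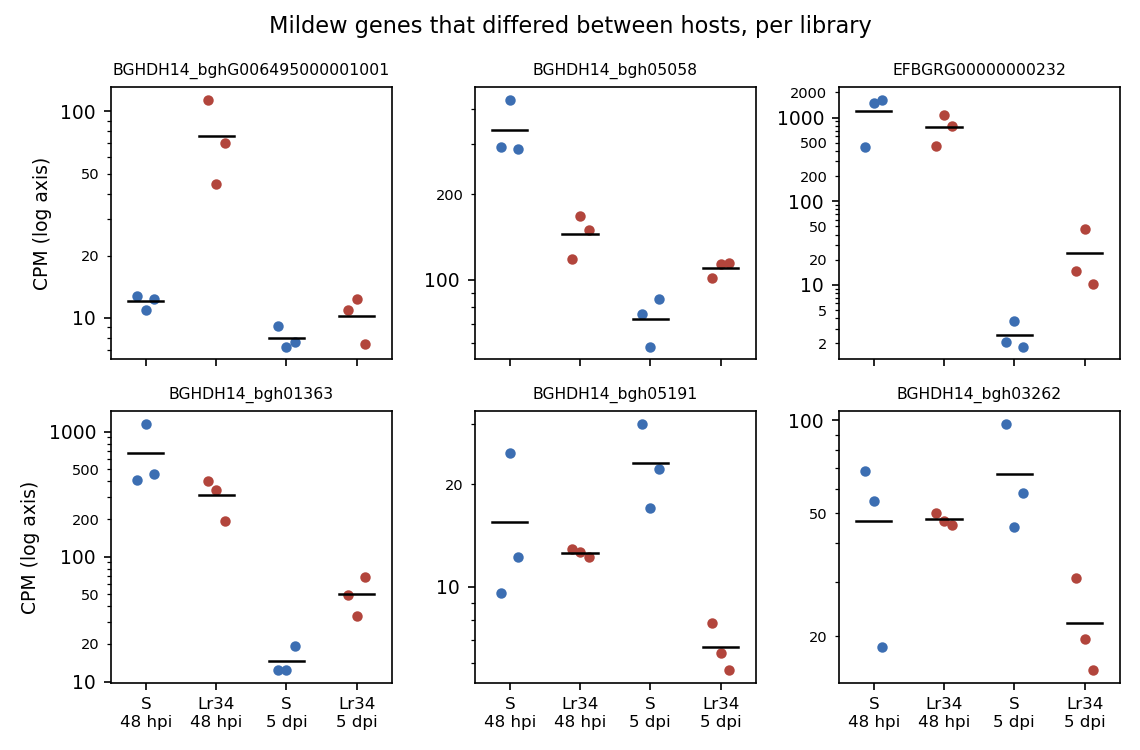
CPM on a log axis (y) of the 6 mildew genes named in the host comparisons, per library in the 4 groups (x; S is susceptible barley, in blue, and Lr34 barley is in red); each point is 1 library and each line a group mean (n = 3). The 2 genes named at 48 hpi separate the hosts at that stage, and the other 4 separate them at 5 dpi.

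Between 48 hpi and 5 dpi the mildew transcriptome changed widely on susceptible barley, with 1086 genes higher and 1071 lower at 5 dpi among 5972 tested. The change was at least 2-fold for 1220 of these 2157 genes. At the extremes, 65 genes were at least 8-fold higher and 78 at least 8-fold lower. BGHDH14_bgh04427 (scaffold HF943530, 1421096 to 1423710, plus strand, 3 exons) reached 156 ± 8.53 CPM at 5 dpi from 1 count in the 3 susceptible 48 hpi libraries together, a 260-fold ratio with a counting interval of 46.6 to 10263. BGHDH14_bgh03665 (scaffold HF943535, 882172 to 882864, minus strand, 2 exons) reached 52.9 ± 3.98 CPM, also from 1 count, an 88.3-fold ratio with a counting interval of 15.8 to 3489. BGHDH14_bgh03782 (scaffold HF943496, 38515 to 39126, minus strand, 2 exons) dropped from 626 ± 363 CPM to 0.674 ± 0.229 CPM, a log2 fold change of -9.74 (SE 0.54, adjusted p = 9.44e-11, edgeR quasi-likelihood test). EFBGRG00000000232 dropped from 1196 ± 657 CPM to 2.53 ± 1.03 CPM, a log2 fold change of -8.82 (SE 0.63, adjusted p = 2.48e-09).

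On Lr34 barley, 686 mildew genes were higher and 624 lower at 5 dpi, and 736 of these 1310 changed at least 2-fold. BGHDH14_bgh03881 (scaffold HF943546, 3638851 to 3640523, plus strand, 2 exons) rose from 5.84 ± 4.72 CPM to 589 ± 61.5 CPM, a log2 fold change of 6.17 (SE 0.31, adjusted p = 1.61e-11). At 48 hpi 14 of its counts were in library 1 and 1 in each of the others, and without library 1 the log2 fold change was 7.55. BGHDH14_bgh00773 (scaffold HF943565, 2949008 to 2950081, minus strand, 1 exon) rose from 1.34 ± 2.33 CPM to 116 ± 24.2 CPM, a log2 fold change of 5.47 (SE 0.59, adjusted p = 7.16e-07), from 5 counts at 48 hpi. All 5 were in library 1, and without it the fitted log2 fold change was 11.77, so the size depends on that library and on the prior count. BGHDH14_bgh03782 dropped here too, from 402 ± 208 CPM to 0.611 ± 0.590 CPM, a log2 fold change of -9.06 (SE 0.57, adjusted p = 1.2e-09), and -9.77 without Lr34 5 dpi library 3. BGHDH14_bgh04105 (scaffold HF943554, 366470 to 366883, minus strand, 2 exons) dropped from 692 ± 213 CPM to 2.06 ± 0.836 CPM, a log2 fold change of -8.28 (SE 0.34, adjusted p = 1.68e-12). Total fungal counts, as geometric means, were 16.9-fold higher at 5 dpi on susceptible barley and 7.10-fold higher on Lr34 barley (exact two-sided permutation tests, p = 0.1 each, the smallest possible). Lr34 48 hpi library 1 held 1.27 M counts, against 0.324 and 0.310 M in libraries 2 and 3, so the Lr34 ratio would be larger without it. Without Lr34 48 hpi library 1 the count of called genes was 795, and without Lr34 5 dpi library 1 it was 830.

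The stage changes on the 2 hosts come from separate libraries and largely went the same way. Of the genes higher at 5 dpi, 520 were called on both hosts, where independent lists would share 125. Of the genes lower at 5 dpi, 450 were called on both, against 112 for independent lists. In opposite directions, 2 genes were higher on susceptible and lower on Lr34 barley, and 1 gene was lower on susceptible and higher on Lr34 barley. Across all tested genes the log2 fold changes of the 2 hosts had a Pearson r of 0.755, a value across genes, which are not independent replicates.

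**Figure D3:**
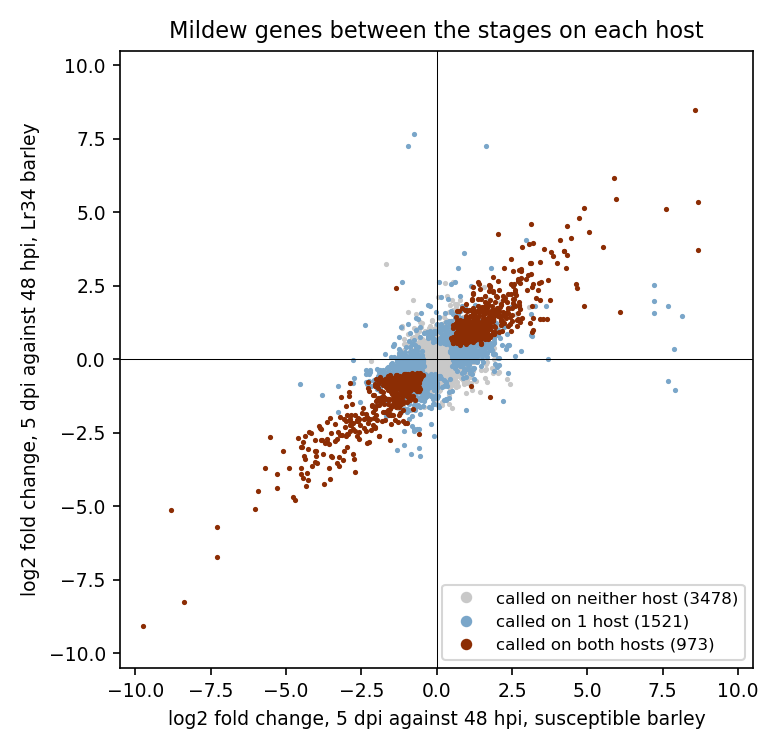
Log2 fold change between 5 dpi and 48 hpi on susceptible barley (x axis) and on Lr34 barley (y axis); each point is 1 of 5972 mildew genes, coloured by whether it was called on both hosts (973 genes), on 1 host (1521) or on neither (3478). The genes called on both hosts lie along the diagonal apart from 3 with opposite signs; fitted values of genes with almost no counts in a group depend on the prior count.

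Short gene models were shifted towards lower expression at 5 dpi on both hosts. On susceptible barley 37.9% of the 485 short models were called lower, against 16.2% of the other genes, and 6.80% were called higher, against 19.2%. Their median log2 fold change was -0.61 against 0.08 (camera, adjusted p = 4.77e-12, and adjusted p = 0.685 with an estimated correlation). Without the second susceptible 48 hpi library, which was relatively high for short models, the median was -0.28 (adjusted p = 2e-07). On Lr34 barley 25.6% of short models were called lower, against 9.11% of the rest, with a median of -0.30 (adjusted p = 1.17e-06, and adjusted p = 0.676 with an estimated correlation). Models of 3000 bp or more had a median of 0.22 on susceptible barley (adjusted p = 0.0330), where the adjusted p was 0.949 with an estimated correlation and 0.930 without that library, and this call also ended without susceptible 5 dpi library 1 or 2. On Lr34 barley their median was -0.02 (adjusted p = 0.832). Camera called no class by exon number or by scaffold between the stages. Fry called, on susceptible and Lr34 barley in this order, models with 5 or more exons (adjusted p = 0.00195 and 0.0183). It also called scaffolds HF943535 (0.00853 and 0.00119), HF943546 (0.00192 and 0.00983), HF943547 (0.0239 and 0.0183) and HF943548 (0.0346 and 0.0200). The median log2 fold changes of these scaffolds were small, from -0.08 (HF943547 on Lr34 barley) to 0.09 (HF943546 on susceptible barley). On susceptible barley alone fry called models with 1 exon (0.0427), scaffold HF943526 (0.0346) and short models (0.00853, against 0.0598 on Lr34 barley).

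The difference between hosts changed between the stages for 37 mildew genes, 20 with a more positive Lr34 effect at 5 dpi and 17 with a more negative one. Of the 37, 2 were also called between hosts at 48 hpi and 14 at 5 dpi. The fitted host difference had opposite signs at the 2 stages for 36 of them, which a test for interaction favours. It was larger in size at 48 hpi, the shallower stage, for 21. Across all tested genes the host log2 fold changes at the 2 stages had a Pearson r of -0.070, a value across genes. BGHDH14_bghG005930000001001 (scaffold HF943524, 78718 to 79110, minus strand, 2 exons) was at 28.1 ± 3.11 CPM on Lr34 and 109 ± 19.8 CPM on susceptible barley at 48 hpi. At 5 dpi it was at 15.7 ± 7.61 CPM and 4.65 ± 1.99 CPM, so its interaction was 3.71 on the log2 scale (SE 0.53, adjusted p = 0.00402). BGHDH14_bgh00631 (scaffold HF943523, 334917 to 335773, minus strand, 2 exons) had an interaction of 3.79 (SE 0.79, adjusted p = 0.0358), with 6 counts on Lr34 barley and 39 on susceptible barley at 48 hpi. The size was 2.61 without Lr34 48 hpi library 1 and 5.15 without library 3. BGHDH14_bghG006495000001001, one of the genes called at 48 hpi, had an interaction of -2.42 (SE 0.55, adjusted p = 0.0493), with a host log2 fold change of 0.33 at 5 dpi. BGHDH14_bgh03665 had an interaction of -4.47 (SE 0.95, adjusted p = 0.0363), a size that rests on 1 count on susceptible barley at 48 hpi, against 22 on Lr34 barley.

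The number of genes with an interaction moved with the libraries used. Without Lr34 48 hpi library 1, 2 or 3 it was 8, 15 and 16, and without Lr34 5 dpi library 1, 2 or 3 it was 15, 63 and 6. Without susceptible 48 hpi library 2 or 3 it was 68 and 94, and without susceptible 5 dpi library 1 or 2 it was 24 and 6. DESeq2 called 218 genes, 141 in the positive direction and 77 in the negative, while limma-voom called 37, 28 positive and 9 negative. The 37 of edgeR shared 36 genes with DESeq2 and 21 with limma-voom. Of the named genes, only BGHDH14_bghG005930000001001 stayed called with each library left out. BGHDH14_bghG006495000001001 stayed called only without Lr34 48 hpi library 2 or Lr34 5 dpi library 2, and its adjusted p reached 0.193 without Lr34 5 dpi library 3. Its call also ended with RLE size factors (0.0567), a minimum count of 50 (0.0557) and limma-voom (0.0613). BGHDH14_bgh00631 lost its call without Lr34 48 hpi library 1 (adjusted p = 0.151) or 2 (0.0618), Lr34 5 dpi library 1 (0.0783) or 3 (0.104), or susceptible 5 dpi library 1 (0.0532) or 2 (0.0917). BGHDH14_bgh03665 lost its call without the same 6 libraries, with an adjusted p of 0.104 at most, and without Lr34 48 hpi library 3 (0.0670) or susceptible 48 hpi library 1 (0.0516), where it had 0 counts left in that group and a fitted interaction of -9.05. Short models had a median interaction of 0.39 (adjusted p = 3.36e-06), and models of 3000 bp or more had -0.24 (adjusted p = 3.36e-06). The adjusted p was 0.629 for both with an estimated correlation and 0.487 for both without susceptible 48 hpi library 2.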

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

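Of the tests below, thinning to equal depth was chosen only after the counts of called genes had been seen, and the reading of the stage score was changed after its values were seen.

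The host effect differed between the stages for 37 mildew genes by the interaction test itself, which is what brought them here. The named ones were BGHDH14_bgh00631 with a log2 interaction of 3.79, BGHDH14_bghG005930000001001 with 3.71, BGHDH14_bgh03665 with -4.47 and BGHDH14_bghG006495000001001 with -2.42. When the hosts were regrouped at random within each stage, 1 of 100 splits, the real one, called as many genes, and the highest of the others called 3. Such splits mix the hosts, so any host difference adds to the spread between libraries and lowers the number they call. They ask whether there is no host effect at all, not whether there is no interaction. Chance is therefore not excluded as the source of the count, which also moved with the libraries used.

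In edgeR more mildew genes differed between hosts at 5 dpi (27) than at 48 hpi (2), and total fungal counts on Lr34 barley were 2.31-fold lower at 5 dpi, by geometric means. The order of the stages depends on the tool and threshold. DESeq2 called 134 genes at 5 dpi and 158 at 48 hpi, and limma-voom 141 and 0. An unadjusted p under 0.05 in edgeR was found for 587 and 1093. EdgeR fits of the 2 compared groups alone, which share no spread between the stages, called 117 and 0. Lower depth at 48 hpi may account for the difference between the stages. With all mildew libraries thinned to the shallowest total, a median of 7 genes was called at 5 dpi, between the bounds set beforehand of 4 or fewer if depth were the cause and 14 or more if not, so this cannot be told apart. At that depth 48 hpi had a median of 11 genes. The thinned fits shared the spread of each gene between the stages, while the groups of unthinned libraries differed in spread. Coefficients of variation were 0.202 on Lr34 and 0.276 on susceptible barley at 48 hpi, and 0.145 and 0.153 at 5 dpi. The counts of 7 and 11 therefore do not compare the size of the host response between the stages.

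Slower development of the fungus on Lr34 barley, as a source of the 27 host-dependent genes and the lower totals at 5 dpi, is a biological hypothesis: on a stage score from 0 (48 hpi) to 1 (5 dpi), computed without the library scored, Lr34 libraries at 5 dpi had a mean of 0.950 ± 0.044 and susceptible ones 1.02 ± 0.078 (difference -0.073, exact permutation p = 0.2, n = 3), so the scores overlapped. At 48 hpi the means went the other way, 0.194 on Lr34 and 0.053 on susceptible barley (difference 0.141, exact permutation p = 0.2, n = 3). Overlap had been set beforehand as evidence against slower development, but with 3 libraries on each host and a lower mean on Lr34 barley it does not exclude a small delay, so slower development and its absence cannot be told apart.

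For the comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In leaf rust the real split called 0 genes and the highest other 1, so 10 of the 10 splits called as many. In the other 4 comparisons 1 of the 10 splits, the real one, called as many. The host comparison at 48 hpi called 2 genes against 1 in the highest other split, that at 5 dpi 27 against 0, the stage comparison on susceptible barley 2157 against 0, and that on Lr34 barley 1310 against 0.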

How the results depend on the processing

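Thinning and the alternatives for gene model classes were added after the data had been examined; the rest were fixed beforehand. The list tests and their alternatives were not run, because gene IDs have no names in the files.

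Both stage comparisons kept their counts within 1.5 times under RLE size factors, the low count filters, DESeq2, limma-voom, the replicate block and a fit of the 2 groups alone. On susceptible barley a fold change of at least 2 left 1220 genes and an adjusted p below 0.01 left 1412, and leaving out 1 library gave 1665 to 2067. On Lr34 barley these counts were 736, 761 and 795 to 1268, and thinning gave 868. Smaller counts moved more, and beyond stricter thresholds and fewer libraries the cause was not tested. In leaf rust the count of 0 became 3 with DESeq2, and 0 to 5 with a library left out. At 48 hpi the 2 host genes became 10 with no filter, 158 with DESeq2, 0 with limma-voom, 0 at an adjusted p below 0.01, 0 with the 2 groups alone, 11 after thinning, and 0 to 122 with a library left out. At 5 dpi the 27 host genes became 134 with DESeq2, 141 with limma-voom, 8 at an adjusted p below 0.01, 117 with the 2 groups alone, 7 after thinning, and 2 to 28 with a library left out. The 37 interaction genes became 24 with RLE size factors, 218 with DESeq2, 4 at an adjusted p below 0.01, 18 after thinning (2 to 34 between the 5 draws), and 6 to 94 with a library left out.

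Libraries of different groups with the same replicate number did not deviate together, with correlations across genes from -0.58 to 0.27, so the numbers are not taken as pairs. With the number as a replicate block, rust had 4 called genes, the host comparisons 0 at 48 hpi and 18 at 5 dpi, the stage comparisons 1968 and 1143, and the interaction 17. Of the named genes, PTTG_07625 newly passed (adjusted p = 0.000321), and calls ended for both 48 hpi host genes and for 3 interaction genes, BGHDH14_bgh00631 (0.0705), BGHDH14_bgh03665 (0.0682) and BGHDH14_bghG006495000001001 (0.0772).

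Of the 14 gene model classes, camera called 4 in rust, 2 at 48 hpi, 1 at 5 dpi, 2 and 1 between the stages on susceptible and Lr34 barley, and 2 for the interaction. With an estimated correlation the number was 0 in each of these 6 comparisons. Leaving out a library gave 0 to 4 in rust, 1 to 2 at 48 hpi, 0 to 1 at 5 dpi, 1 to 2 and 1 to 1 between the stages, and 0 to 2 for the interaction. RLE size factors and the block changed none of these counts. Fry called classes only between the stages. With the gene ID series as classes, 2 series were called in rust, 2 at 48 hpi, 2 for the interaction and 0 elsewhere. With an estimated correlation both rust calls were lost (adjusted p = 0.535 and 0.051), as was 1 series at 48 hpi (0.120) and for the interaction (0.0927). The bgh series stayed called there (0.00474 and 0.00280), with medians of at most 0.01 in size over its 5202 genes. It holds most tested genes, and the medians of the rest were 0.148 at 48 hpi and -0.165 for the interaction.

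For the 22 named results, 141 values under other settings included 124 on the same side of the threshold, 14 that missed it and 3 that newly passed it. No value was available where DESeq2 gave no adjusted p (BGHDH14_bgh05191, BGHDH14_bgh03262 and BGHDH14_bgh00631) or a minimum count of 50 removed the gene (BGHDH14_bgh05191 and BGHDH14_bgh00631). Leaving out a library gave 156 values, of which 111 stayed, 44 missed the threshold and 1 newly passed it. None changed direction. The log2 ratio of total counts at 5 dpi ranged from -0.83 to -1.45 with a library left out. Depth limits low genes at 48 hpi, where a count of 0 allows up to 9.69 CPM in the shallowest library. The spread between libraries (coefficient of variation 0.276 in the susceptible 48 hpi group) is another limit there, and they were not separated.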

Other observations

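Tests chosen only after the data had been examined were the exon length of the genes with 8-fold changes, also with a library left out, the length slopes of the rust libraries, and the neighbour counts other than that of genes lower on susceptible barley. That count had been set out for the genes with an 8-fold drop and was assigned to all genes lower at 5 dpi after its value was seen. For host reads and for another stage of infection, the bounds against them had been set for the value alone, and that its whole interval must lie within them was required only after the values were seen.

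The mildew genes that dropped most between the stages were mostly short. At least 8-fold lower at 5 dpi on both hosts were 40 genes, and 29 of them (72.5%) had a summed exon length under 600 bp, against 8.12% of the 5972 tested genes (Fisher's exact test across genes, p = 1.08e-23). With each mildew library left out in turn there were 30 to 48 such genes, 69.2% to 79.2% of them short, and without the second susceptible 48 hpi library, which was relatively high for short models, 35 genes, of which 34 were shared and 25 (71.4%) were short. The median length of the 40 was 480 bp, against 1346 bp for all tested genes. The 27 genes at least 8-fold higher at 5 dpi on both hosts had 3 short models (11.1%, Fisher's exact test p = 0.479) and a median length of 1107 bp. Genes are not independent replicates, so these p-values describe the list only.

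Host reads counted in fungal models were weighed as a source of the 8-fold drop, since host reads would weigh more when the fungus is scarce. If their number stayed constant, the 40 genes would be 1.21 higher on Lr34 barley at 5 dpi on the log2 scale, where fungal totals were lower. Their median host log2 fold change was 0.25 (95% bootstrap interval 0.083 to 0.467, quartiles -0.11 and 0.59), and 0.11 to 0.49 for the lists made with a library left out. This median lies below the 0.6 set as needed and within the 0.3 set as the bound against host reads, but its interval passes 0.3. It cannot decide, because fungal totals rose 7.10-fold on Lr34 barley between the stages. A constant number of host reads would drop by about that much there, short of the 8-fold cut. The list therefore tends to leave such genes out beforehand, and it was chosen on the same 5 dpi libraries. Raw counts on susceptible barley were lower at 5 dpi for 18 of the 40 (median ratio 1.04, which choosing genes by an 8-fold drop partly sets), and they fell from 763 to 19 for BGHDH14_bgh03782 and from 1361 to 72 for EFBGRG00000000232 (1176 to 228 on Lr34 barley), which a constant number of host reads would not give. Host reads whose number changed with the stage or with the total reads per library, which are not in the tables used, and a programme of early infection genes, an untested biological hypothesis, cannot be told apart for the 40 genes as a set.

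Neighbouring mildew genes tended to drop together. On susceptible barley 220 neighbouring pairs were both lower at 5 dpi, against a mean of 183 and an upper limit of 206 for the middle 95% of 10000 shuffles of the calls (one-sided permutation p = 0.001, adjusted p = 0.002 over the 10 counts made). On Lr34 barley there were 99 pairs against 62.3 (permutation p = 1e-04, the smallest that the shuffles can give). With gaps of at least 1 kb the pairs were 176 against 140 and 96 against 47.7. Genes higher at 5 dpi did the same, with 226 pairs against 189 on susceptible barley and 116 against 75.1 on Lr34 barley. The counts exceed what calls placed at random over the tested genes give. The shuffles did not match genes by expression level or exon length, so neighbours alike in these were not excluded as a source. Shared regulation of neighbours is a hypothesis that was not tested. The 40 genes with an 8-fold drop held 1 such pair against 0.243 (permutation p = 0.2), too few pairs to decide.

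The second susceptible mildew library at 48 hpi stood apart from the other 48 hpi libraries. Depth does not account for this, since after 1 random thinning to equal depth its mean correlation with the others was 0.860, while the other 5 libraries had 0.883 or more. Another stage of infection stays open: its stage score of -0.086 was the lowest of the 12 mildew libraries, while across genes its deviation from the other susceptible libraries had an r of -0.097 with the stage change on Lr34 barley (95% bootstrap interval -0.135 to -0.059), short of the 0.3 in size set as needed and within the 0.1 set as the bound against it, which its interval passes. Its deviation followed summed exon length (Spearman rho = -0.483 across genes), as a gene length bias in that library, from RNA quality or library making, would give. Other mildew libraries had such slopes too, with a rho of 0.353 for susceptible 48 hpi library 3 and -0.311 for susceptible 5 dpi library 3. Each library was set against the others of its group, so slopes within a group are not independent. The alignment of the second susceptible 48 hpi library carries a second mapping tag. The first Lr34 rust library shares this tag, and its deviation had a rho of 0.118 with length. A difference in mapping stays open, as does a true difference of short genes in the leaves of that mildew library.

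Rust libraries varied more on susceptible wheat than on Lr34 wheat, with biological coefficients of variation of 0.284 and 0.172, a difference that was not tested. The deviations of susceptible rust libraries 1 and 3 from their group had a Spearman rho with coding length of 0.349 and -0.369, while no Lr34 rust library exceeded 0.118 in size. Across the 6 rust libraries 96 of 7389 genes spanned at least 8-fold, 30 genes did so among the susceptible libraries and 15 among the Lr34 libraries.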
